A study of Caenorhabditis elegans with 2 samples.

How the data were processed

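Chromatin immunoprecipitation followed by sequencing was carried out on whole young adult Caenorhabditis elegans hermaphrodites, collected 64 h after synchronization of starved L1 larvae, per the labels. The strain OP478 carries an integrated transgene that expresses the protein encoded by T07F8.4 with GFP and FLAG tags at its C terminus, together with an unc-119 rescue of an unc-119 mutation, and an antibody against GFP was used. Per the labels, the 2 samples are biological replicates of this single group. Immunoprecipitated samples of other strains, untagged animals or input DNA were not analysed here, so no comparison between groups was made.

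The deposited files used were 8 peak lists, 4 on build ce11 and 4 on build ce10. For each build there was a list of regions for each replicate and one for both replicates pooled. The authors labelled the pooled one as peaks and background. The last was a list of reproducible peaks that the authors selected by the irreproducible discovery rate (IDR) from the other 3. Per the deposited descriptions of the files, the replicate and pooled lists were each made from the replicate alignments and 1 further file, which also went into the control-normalized signal and was taken here to be the control. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each peak carried a signal value written by the authors' peak caller, whose scale is not given in the sources used here. In the deposited lists the q-value of each peak stood as −log10, and it reached the same upper value for 421 of the 621 reproducible peaks on ce11, so peaks were ranked by the authors' signal value. Each signal value is the peak's own value in its own list, and signal values were used only to rank, filter and describe peaks within a list. Read depth is unknown, because the lists hold no read counts.

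Coordinates are 1-based on ce11 (WBcel235), and the genome sequence and the Ensembl release 115 annotation of that build were used. No coordinate was converted between builds, and ce10 lists were not annotated. The reproducible list of ce11 consisted of exactly the 621 regions of the pooled list with the highest signal values, and that of ce10 of the 768 highest. Enrichments were computed against the 16150 regions of the pooled ce11 list that did not overlap a reproducible peak, since these could have passed the same selection. That background held no mitochondrial region, because a single reproducible interval spanned most of the mitochondrial genome.

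Summits within 100 bp of each other were counted as shared, and the chance level was the mean over 1000 circular shifts of the replicate list within each chromosome, tested one-sided; 0.001 is the smallest p these shifts can give. A summit was put in a promoter when it lay from 500 bp upstream to 100 bp downstream of an annotated transcript start, and otherwise in the 5' UTR, CDS, 3' UTR, non-coding RNA exon, intron or intergenic class, in that order. Each summit was assigned to the gene with the nearest transcript start within 1000 bp. Shares were compared with two-sided Fisher's exact tests, with odds ratios computed after adding 0.5 to each cell and with 95% Woolf intervals. P-values were adjusted by the Benjamini-Hochberg method over the 7 classes, 7 chromosomes, 30 gene lists, 10 biotypes or 2080 6-mers of each family. Neighbouring peaks and genes, and tRNA genes of identical sequence, are not independent replicates. These p-values therefore describe the lists and not the spread between animals. Canonical 6-mers within 50 bp of the summits were tested against 5 background windows per summit matched on GC content in bins of 5 percentage points, first on chromosomes I, II and III and then on IV, V and X. Median GC content was compared by a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05. Genes that opened a run of same-strand protein-coding genes with gaps under 500 bp were called operon-like. tRNA isotypes were taken from the RefSeq annotation of the same assembly, which named one for 607 of 612 nuclear tRNA genes.

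The tests, gene lists, alternatives and naming rule were fixed before the data were examined. The rule named the 25 reproducible peaks with the highest signal that had a summit in both replicate lists, up to 4 members of each gene list past an adjusted p of 0.05, T07F8.4, unc-119 and genes with a reproducible peak within 20 kb of them, and the 10 6-mers with the smallest p among those past the threshold in both chromosome sets. Of the 25 peaks, 19 were mitochondrial, so further nuclear peaks, the tRNA isotypes, the members of gene lists that did not pass, and the X chromosome peaks without a transcript start were named after their values were seen. The name patterns of the lists also took in 28 genes outside their subject, such as unc-40 in the homeobox list and the srp serpins in the chemoreceptor list. Of these, 10 were among the tested genes and 1 had a peak, rpac-19 in the cell cycle list.

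Alternatives fixed before the data were examined were the 310 peaks with the highest signal, each replicate's own list in place of the combined one, the ce10 lists, other rules for shared summits, other promoter windows, distances and 6-mer windows, and other backgrounds. Alternatives restricted to nuclear peaks, to protein-coding genes or transcript starts, to peaks not assigned to tRNA genes, or to peaks neither assigned to a tRNA gene nor within 100 bp of one were chosen after seeing the data. For the replicate alternatives, the 621 highest peaks of a single replicate were compared with the rest of that replicate's list.

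Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, edlib 1.3.9.post1 and matplotlib 3.10.9. The scripts were tested on simulated data. A 6-mer written into 25.0% of background windows was recovered in 5 of 5 runs, and 0 of 2080 6-mers were called with nothing written in. For the gene lists, 18.5% of the tested members of a list added to random genes were recovered in 20 of 20 runs, and 1 of 20 runs with none added called a list. For the replicate overlap, a list made to hold 59.9% of the 621 summits gave an estimate of 59.8%. That estimate subtracted a chance term computed from the planted share itself, so the match is partly built in. The overlaps given below carry no such correction. Random background summits differed in GC content at p under 0.05 in 2 of 20 runs.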

Results

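Chromatin regions recovered with an antibody against GFP from whole young adult C. elegans that express the GFP-tagged protein encoded by T07F8.4 were described from 2 biological replicates. Untagged animals and other tagged proteins were not analysed here, so the peaks are those of the immunoprecipitation. The authors' reproducible list held 621 peaks on build ce11, of which 600 were nuclear and 21 mitochondrial. The lists from which it was made held 19514 regions for replicate 1, 17499 for replicate 2 and 16958 for the pooled replicates. Median width was 436 bp. As 512 of the 621 reproducible peaks and 16845 of the 16958 pooled regions had exactly this width, it does not measure the extent of binding. The authors' signal value of the reproducible peaks ran from 68.2 to 7916 with a median of 92.3. Read depth behind each peak is unknown.

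The 19 highest signal values lay on the mitochondrial genome. All 21 mitochondrial summits shared a single interval, positions 4 to 13412 of a genome of 13794 bp, which it covered to 97.2%. The highest value, 7916, was at position 4732, 228 bp inside gene WBGene00000829, and was 21.7 times the highest nuclear value. Mitochondrial summits filled 19 of the 25 highest places in the replicate 1 list and 22 of 25 in the replicate 2 list.

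The highest nuclear peaks included several at genes for small structural RNAs. The highest of them was at C51F7.4, a small nucleolar RNA (snoRNA) gene of the class that guides the modification of other RNAs, on chromosome V from 12303495 to 12303805, with a signal value of 364.2. It was followed by the snoRNA gene ZK994.7 on chromosome V from 8500392 to 8500698, with 331.8. Then came the upstream regions of the protein-coding genes K12H4.5 (chromosome III from 8043832 to 8044116, 294.2) and tasp-1, a TASPase homolog (chromosome III from 10759127 to 10759391, 256.6). The snoRNA gene T03F7.8 on chromosome V from 11314078 to 11314355 had 254.6. The RNA component of RNase P, rpr-1, an enzyme that trims precursor tRNAs, on chromosome I from 13463816 to 13464128, had 245.2. In the separate replicate lists these 6 peaks had signal values of 159 and 205 (C51F7.4), 182 and 146 (ZK994.7), 174 and 123 (K12H4.5), 152.0 and 105 (tasp-1), 125 and 135 (T03F7.8), and 133.8 and 111.6 (rpr-1) in replicates 1 and 2.

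Of the 600 nuclear peaks, 209 were assigned to tRNA genes, 147 to protein-coding genes, 88 to genes annotated as ncRNA, 63 to snoRNA genes and 13 to snRNA genes, while 65 had no transcript start within 1000 bp. Counted as genes and with the mitochondrial genes included, 215 of the 404 tRNA genes with any region in the pooled list had a reproducible peak, or 53.2% (95% Wilson interval 48.3% to 58.0%). The shares were 36.6% for snoRNA genes (63 of 172), 20% for snRNA genes (11 of 55), 6.09% for ncRNA genes (86 of 1411) and 2.58% for protein-coding genes (150 of 5806). By Fisher's exact test with Benjamini-Hochberg adjustment, tRNA genes (odds ratio 27.6, 95% interval 22 to 34.5, adjusted p = 2.76e-162), snoRNA genes (9.69, 7.02 to 13.4, adjusted p = 2.25e-32) and snRNA genes (3.93, 2.04 to 7.55, adjusted p = 0.001) were enriched. By the same exact test, protein-coding genes (odds ratio 0.166, adjusted p = 3.71e-83), piRNA genes (3 of 447, odds ratio 0.112, adjusted p = 3.19e-09) and pseudogenes (5 of 229, odds ratio 0.36, adjusted p = 0.013) were depleted. Each summit went to only 1 gene, so the many tRNA and snoRNA genes lower the share left for other classes. With protein-coding transcript starts only, 316 of 6429 protein-coding genes had a peak, and summits were enriched in their promoters (odds ratio 1.41). The pseudogene call was lost among the 310 peaks with the highest signal (odds ratio 0.32, adjusted exact p = 0.0596). The ncRNA class as a whole did not differ from the background (odds ratio 0.971, adjusted exact p = 0.9), and neither did miRNA, rRNA or lincRNA genes.

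**Figure D1:**
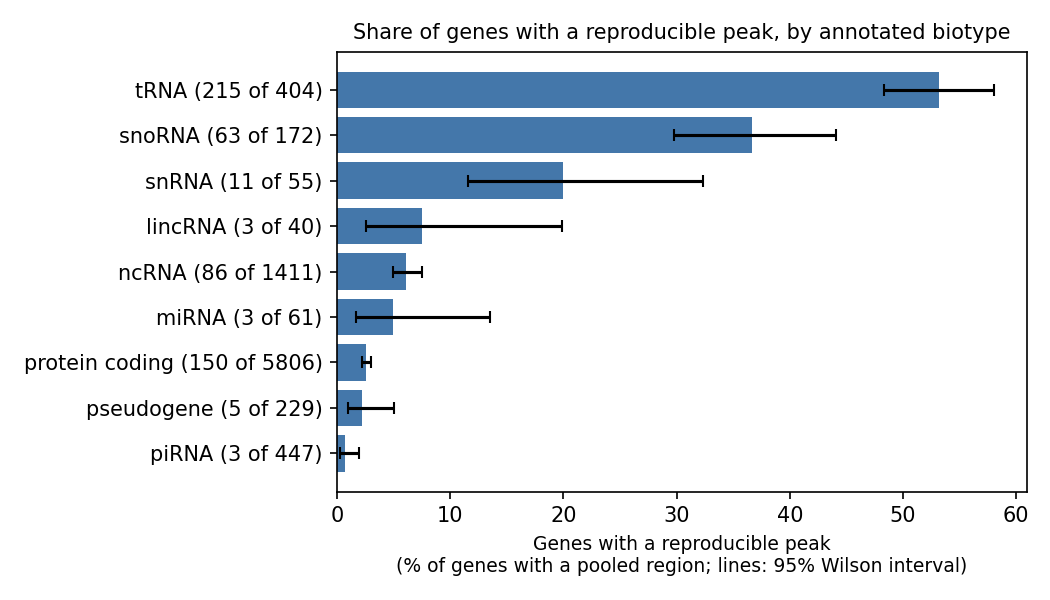
Share of genes of each annotated biotype (rows, with counts) that had a reproducible peak, in percent of the genes of that biotype with any region in the pooled list; lines are 95% Wilson intervals, and biotypes with fewer than 10 such genes are left out. tRNA genes stand at 53.2%, snoRNA genes at 36.6% and protein-coding genes at 2.58%.

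The snoRNA genes had the highest signal values as a class, with a median of 136 against 94.0 at tRNA genes, 88.9 at ncRNA genes and 81.2 at protein-coding genes, and they held 18 of the 50 highest nuclear peaks. Among the snRNA genes were the spliced leader RNA genes sls-2.1 (chromosome II from 5844663 to 5844870, signal value 212.2), sls-2.4 (chromosome I from 4172113 to 4172500, 174.0) and sls-2.8 (chromosome III from 12250247 to 12250682, 97.4), whose products are joined to the 5' ends of downstream mRNAs of operons. Peaks at other structural RNAs included mrpr-1, the RNA of RNase MRP (chromosome II, summit at 7200360, 131.1), and srpr-2.2, named for the signal recognition particle RNA (chromosome III, summit at 5031603, 112.5).

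Summit position differed between the classes. At tRNA genes the median summit lay 8 bp inside the transcript start (quartiles -16 and 27 bp, where negative values are upstream), and 207 of 209 summits were within 100 bp of it. At snoRNA genes the median was -40 bp (quartiles -52 and -17), with 50 of 63 summits upstream of the start. At protein-coding genes the median was -179 bp (quartiles -311 and -58.5), with 123 of 147 summits upstream and 32 within 100 bp. Background regions at tRNA genes also centred on the gene, with a median of 4 bp, whereas those at snoRNA and protein-coding genes had medians of 30 and 18 bp.

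**Figure D2:**
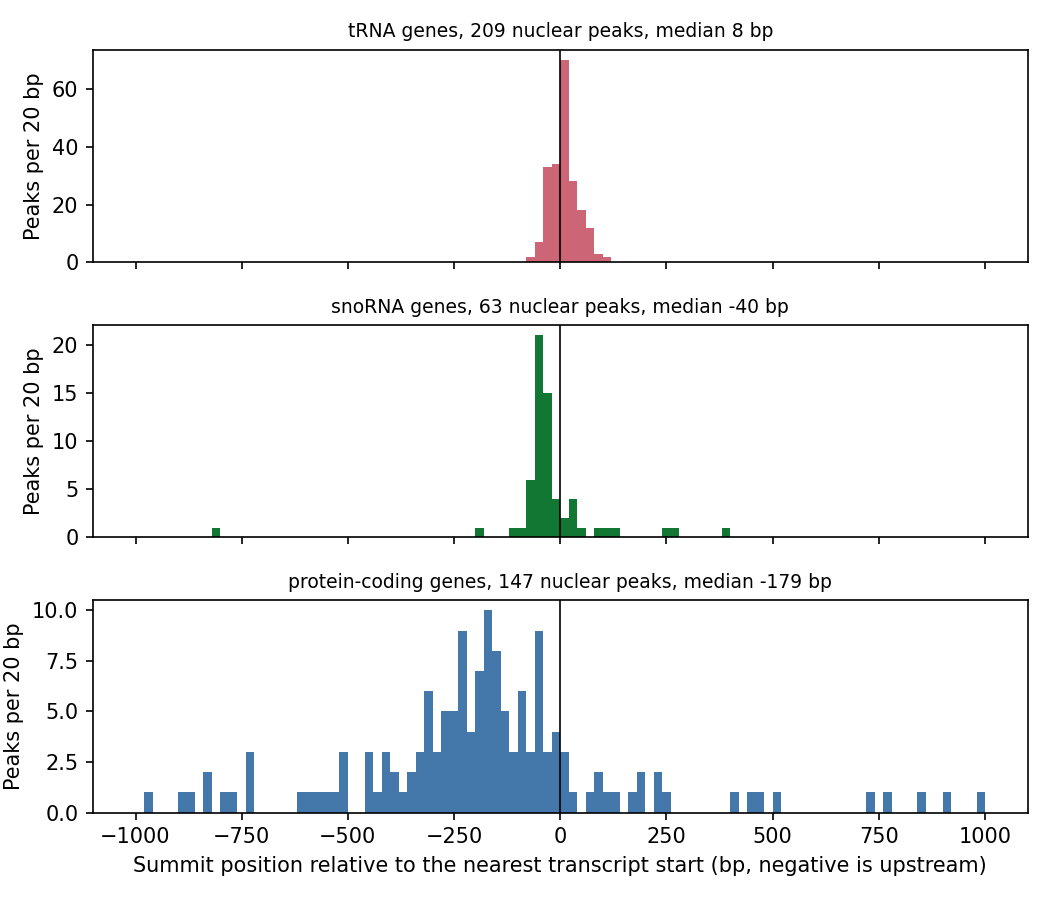
Position of the summit relative to the nearest annotated transcript start (horizontal axis, bp, negative is upstream) for nuclear reproducible peaks at tRNA, snoRNA and protein-coding genes; the vertical axis counts peaks per 20 bp. Medians are 8, -40 and -179 bp.

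Of the 612 annotated nuclear tRNA genes, whether or not they had a pooled region, 209 had a reproducible peak assigned to them, or 34.2% (95% Wilson interval 30.5% to 38%). This leaves out summits assigned to other genes: 245 nuclear summits lay within 100 bp of a tRNA gene, 36 of them assigned elsewhere, and 260 tRNA genes had a summit that close, counting neighbouring genes that share one. Peaks were found at genes of 20 of the 21 annotated isotypes, the exception being the single gene for selenocysteine tRNA. The share ran from 61.5% of cysteine (8 of 13), 55.9% of threonine (19 of 34) and 52.9% of alanine tRNA genes (18 of 34) to 15% of histidine (3 of 20) and 14.3% of phenylalanine tRNA genes (2 of 14). None of the 21 isotypes differed from the others after adjustment by Fisher's exact test. Threonine had the smallest exact p (0.00897, adjusted p = 0.188), and alanine had an unadjusted p of 0.0251. The highest tRNA peaks were at a glycine tRNA gene, WBGene00023110 (chromosome X from 3036024 to 3036279, signal value 203.8), and an alanine tRNA gene, WBGene00023049 (chromosome V from 9318133 to 9318272, 201.1). Many tRNA genes have identical copies, and the handling of reads that align to several copies is not given in the sources used here.

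Among protein-coding genes, those for cytosolic ribosomal proteins were the only one of 30 fixed lists past the threshold when protein-coding genes with a peak were compared with the other protein-coding genes with a pooled region, a test added after the data were seen. Of 57 tested members, 7 had a peak (odds ratio 5.80, 95% interval 2.65 to 12.7, adjusted exact p = 0.0179), led by rpl-3 (signal value 233.9), rpl-15 (199.6), rpl-35 (192.9) and rps-24 (141.4). With each summit assigned to the nearest protein-coding transcript start, 10 of 64 had one (3.81, 1.95 to 7.45, adjusted exact p = 0.0304). The test fixed beforehand took in genes of all biotypes, of which 150 of the 541 with a peak were protein-coding, so any protein-coding list was diluted in it. In that test ribosomal proteins had an odds ratio of 2.24 (1.03 to 4.84, adjusted exact p = 0.663). Chemoreceptors were the only list past the threshold there (0 of 541 genes with a peak against 1.47% of the 8104 others, odds ratio 0.0617, 0.00383 to 0.994, adjusted exact p = 0.025). Among protein-coding genes alone the chemoreceptor call was lost (0 of 150 against 2.10%, odds ratio 0.154, adjusted exact p = 0.46). It also rested on the assignment rule, since with protein-coding transcript starts only 4 of 138 chemoreceptors had a peak (odds ratio 0.64, adjusted exact p = 0.928). Translation factors were represented by eif-3.C (132.5), iff-2 (105.8) and eef-1G (72.9), chaperone genes by dnj-28 (106.2), bag-1 (102.8), dnj-9 (87.9) and hsp-3 (84.8), and the respiratory chain by cox-5A (104.2), cox-6B (89.5) and cox-5B (78.2), none of these lists passing in either test. The name pattern of the respiratory chain list did not match the 8 protein-coding genes of the mitochondrial genome that had a reproducible peak. Of the 30 lists, 19 had no member with a reproducible peak, among them cuticle collagens (0 of 81 tested, adjusted exact p = 0.142), nuclear hormone receptors (0 of 66, adjusted p = 0.348), proteasome, mitochondrial ribosome, splicing, germline, meiotic, small RNA pathway, neuron, muscle and intestine genes. Both p-values come from the diluted test over all biotypes. Only 2.58% of the tested protein-coding genes had a peak (150 of 5806), so zeros are a common outcome for short lists. Some of these zeros rested on the assignment rule: with protein-coding transcript starts only, 3 of 96 collagen, 2 of 75 nuclear hormone receptor, 3 of 36 homeobox, 3 of 38 cytochrome P450, UGT and GST, and 1 each of the mitochondrial ribosome, splicing, germline and meiotic genes had a peak.

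Operon-like genes, which open a run of closely spaced genes on the same strand, made up 23.3% of the protein-coding genes with a peak (35 of 150) and 16.2% of the other protein-coding genes with a pooled region (914 of 5656; odds ratio 1.59, 95% interval 1.09 to 2.34, p = 0.0247, Fisher's exact test). The call was lost in the list of replicate 2 alone (odds ratio 1.39, exact p = 0.116) and with protein-coding transcript starts only (1.24, p = 0.159).

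Promoters of any annotated transcript held 487 of the 621 summits, or 78.4%, against 32.9% of the background regions (odds ratio 7.39, 95% interval 6.09 to 8.97, Fisher's exact test, p = 7.04e-115). Coding sequence held 3.06% of summits against 22.7% of the background (odds ratio 0.11, adjusted exact p = 2.5e-42), introns 4.51% against 20.7% (0.184, adjusted p = 1.55e-29), 3' UTRs 1.61% against 5.63% (0.287, adjusted p = 1.66e-06) and intergenic sequence 10.5% against 16.1% (0.615, adjusted p = 0.00015). The depletion in 3' UTRs was weaker in the list of replicate 2 alone (odds ratio 0.627, adjusted exact p = 0.0444) and did not pass against uniform positions (0.623, adjusted permutation p = 0.232). The promoter window reached 100 bp downstream of the start and was applied first, so summits inside short RNA genes could count as promoter. Of the 600 nuclear summits, 151 lay inside a tRNA gene, and 76 of the 209 assigned to tRNA genes were upstream of the start. The share is therefore not one of upstream sequence alone, and the non-coding RNA exon class leaves out such summits. The promoter excess rested largely on non-coding genes. With protein-coding transcript starts only, the share was 30.8% against 24.0%, and the odds ratio fell to 1.41 (95% interval 1.19 to 1.68, exact p = 0.000157). With peaks assigned to tRNA genes left out of both lists it was 4.40 (3.56 to 5.43).

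Chromosome X carried 165 of the 621 peaks, or 26.6%, against 15.7% of the background regions (odds ratio 1.95, 95% interval 1.62 to 2.34, Fisher's exact test, adjusted p = 3.73e-11). Chromosome V carried 69, or 11.1%, against 17.98% (odds ratio 0.574, adjusted exact p = 1.13e-05), and no other nuclear chromosome passed the threshold in this main setting. On X, 106 of the 165 peaks were assigned to tRNA genes and 120 had a summit within 100 bp of one, and 276 of the 612 annotated nuclear tRNA genes (45.1%) lie there. With peaks assigned to tRNA genes left out of both lists, X held 14.6% of the peaks and 15.3% of the background (odds ratio 0.947, adjusted exact p = 0.923). With those within 100 bp of a tRNA gene left out too, the odds ratio was 0.78 for X (adjusted exact p = 0.215) and 0.707 for V, where the call was lost (adjusted exact p = 0.0533). Chromosome III passed as enriched in both of these settings (odds ratios 1.36 and 1.40, adjusted exact p = 0.0352 and 0.0377). Within tRNA genes, 38.4% of those on X (106 of 276) and 30.7% of those on autosomes (103 of 336) had a peak (odds ratio 1.41, 95% interval 1.01 to 1.97, exact p = 0.0489, a test added after the data were seen). The middle of the autosomes, equal in length to either arm, held 39.8% of autosomal peaks and 38.3% of the background (odds ratio 1.07, exact p = 0.548).

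**Figure D3:**
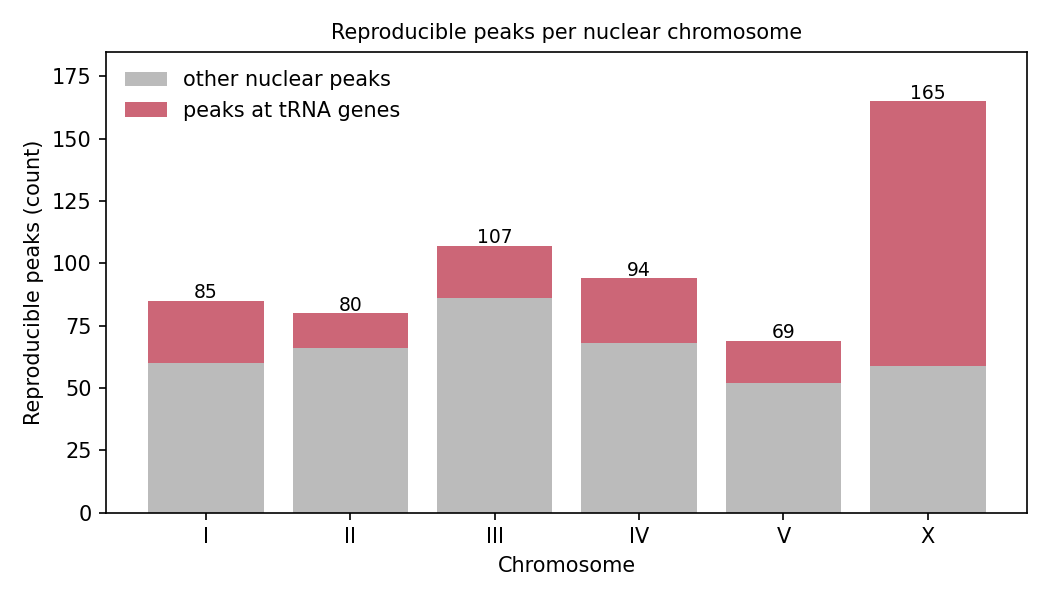
Number of nuclear reproducible peaks per chromosome (vertical axis, count), split into peaks assigned to tRNA genes and other peaks. Chromosome X has 165 peaks, of which 106 are assigned to tRNA genes.

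Several of the highest nuclear peaks on X had no transcript start within 1000 bp. They lay from 6296427 to 6296725 (signal value 244.7, the seventh highest nuclear value), from 4209187 to 4209411 (221.6), from 11094072 to 11094296 (220.7), from 13700808 to 13700947 (210.5) and from 9465764 to 9465970 (207.3). In all, 19 of the 165 X peaks were of this kind.

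Sequence at the summits was richer in GC than at background summits, with a median of 49.5% (SD 8.51) against 40.6% (SD 10.96) within 50 bp (permutation test, p = 1e-05, the smallest it can give). After matching on GC, 46 canonical 6-mers were enriched and 14 depleted in both chromosome sets. The windows are not independent, since 469 of the 612 nuclear tRNA genes have an identical copy. The same tRNA sequence may thus be counted several times and in both sets. GTTCGA, which is part of the B box of the internal tRNA promoter, was present at 17.6% of summits on chromosomes I to III against 4.78% of matched windows (odds ratio 4.27, Fisher's exact test, adjusted p = 2.53e-08), and at 24.7% against 5.37% on IV, V and X (5.78, adjusted p = 1.59e-20). Of the other named 6-mers, CGAACC (odds ratios 4.86 and 6.57 in the 2 chromosome sets), ACGCTC (4.34 and 3.52), ACCACT (3.41 and 5.58), AGAGCG (3.56 and 4.31), GAACCC (3.95 and 5.75), CACTCG (3.71 and 3.18), GCTCTA (3.85 and 4.47) and TAACCA (4.08 and 5.65) were enriched. GGAGCA was depleted (0.122 and 0.47), a call lost on IV, V and X in the list of replicate 2 alone (odds ratio 0.587, adjusted exact p = 0.19), among the 310 highest peaks (0.407, 0.122), with a 25 bp window (0.608, 0.554) and without GC matching (0.706, 0.367). With peaks assigned to tRNA genes left out, 3 enriched 6-mers passed in both sets: ACGCGC (odds ratios 3.11 and 3.09), GGCGCA (2.84 and 2.73) and CACTCG (2.83 and 3.04). GTTCGA then had odds ratios of 2.45 and 5.33 and passed only on IV, V and X (adjusted exact p = 0.0687 and 3.04e-07), but the remaining peaks still included 34 assigned to ncRNA genes with a summit within 100 bp of a tRNA gene. With these and all others that close left out as well, GTTCGA had odds ratios of 2.12 and 2.73 and passed in neither set (adjusted exact p = 0.288 and 0.0941). Each of 4 other named 6-mers passed in a single set: TAACCA on IV, V and X (4.84, adjusted exact p = 0.00637), and ACCACT (3.08, adjusted exact p = 0.0317), CACTCG (2.99, adjusted exact p = 0.0329) and the depleted GGAGCA (0.162, adjusted exact p = 0.00871) on I, II and III. The 6-mers that passed in both sets were ACGCGC (3.47 and 3.14) and CGCACA (2.72 and 3.33).

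The transgene was expected to add copies of T07F8.4 (chromosome II from 7130529 to 7132032, minus strand) and unc-119 (chromosome III from 10902641 to 10908935, plus strand). No reproducible peak lay within 20 kb of either gene, where 0.196 and 0.373 were found on average after circular shifts. The pooled list had 5 regions within 20 kb of T07F8.4 and 10 within 20 kb of unc-119, against 7.15 and 9.42 after shifts (permutation p = 0.681 and 0.459). The highest of them ranked 1254 and 3326 among 16958 regions.

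Both replicate lists held regions at most of the reproducible peaks, but they were permissive, with −log10 q-values as low as 0.0176 and 0.0178. A summit in such a list is therefore not by itself a called peak in that replicate. Of the reproducible summits, 78.1% and 78.7% lay within 100 bp of one of the 621 highest summits of replicates 1 and 2. A summit of the replicate 1 list lay within 100 bp of 608 of the 621 summits (97.9%, chance 4.99%), and one of the replicate 2 list within 100 bp of 604 (97.3%, chance 4.67%; permutation p = 0.001 for each, the smallest the shifts can give). In both lists at once, 591 peaks were found, or 95.2%. The 621 highest peaks of replicate 1 shared 376 with the 621 highest of replicate 2 (60.5%, chance 1.38%, permutation p = 0.001). Across the 591 peaks, Spearman's rho between the signal values was 0.557, and it was 0.509 across the 571 nuclear ones, where peaks are not independent replicates. The reproducible list was made from these same lists, so its overlap with each is not independent evidence.

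**Figure D4:**
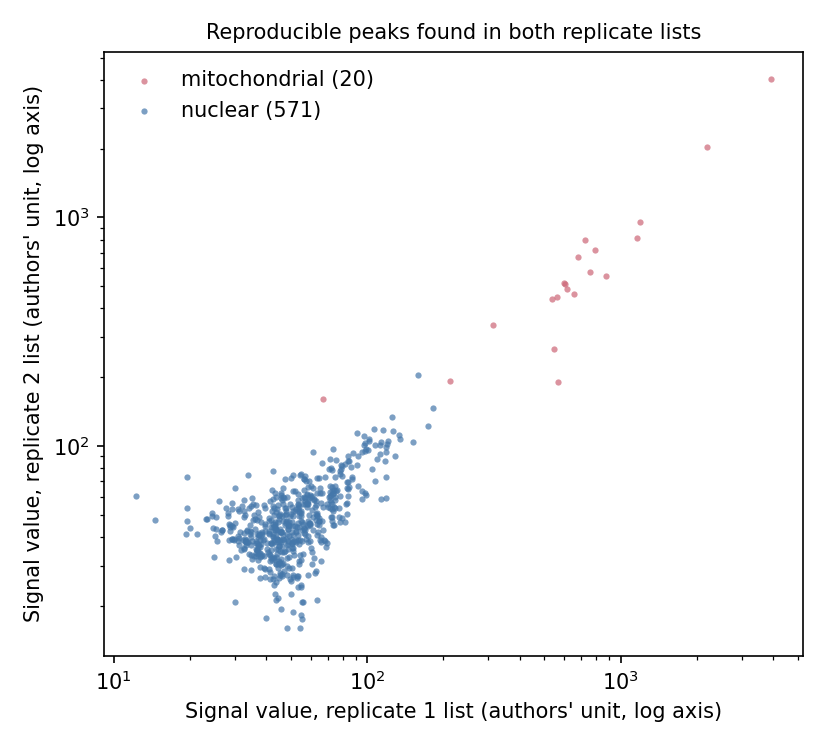
Signal value of each of the 591 reproducible peaks found in both replicate lists, in the list of replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), in the authors' unit; 20 are mitochondrial and 571 nuclear. The mitochondrial summits reach the highest values in both replicates.

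On build ce10 the reproducible list held 768 peaks against 621 on ce11, although the pooled lists were of like length (16950 and 16958 regions). The lowest signal value among the reproducible peaks was 61.8 on ce10 and 68.2 on ce11. X carried 25.1% of the ce10 peaks against 15.7% of the ce10 background (odds ratio 1.81, adjusted exact p = 1.6e-10), and the 768 highest peaks of the replicates shared 57.3%.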

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

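Alternatives restricted to nuclear peaks, to protein-coding genes or transcript starts, to peaks not assigned to tRNA genes and to peaks also over 100 bp from one were chosen after seeing the data. Among the alternatives fixed beforehand, 214 of the recomputed values held, 9 counts moved, 9 values lost the threshold, 3 passed it and 4 turned direction. The promoter, GC, replicate overlap, rank agreement, tRNA, snoRNA, snRNA, X and V results kept their calls under every alternative fixed beforehand in which they were computed. Leaving out peaks assigned to tRNA genes, an alternative chosen later, turned the odds ratio of X to 0.947, no longer past the threshold. Leaving out all peaks within 100 bp of a tRNA gene as well gave 0.78 for X, and 0.707 for V, which lost its call. Other chromosomes passed in some fixed alternatives. Chromosome I was depleted among the 310 highest peaks (odds ratio 0.609, adjusted exact p = 0.00904) and without replicate 2 (0.764, 0.038). Chromosome II was depleted without replicate 1 (0.762, 0.0435). Chromosome III was enriched against uniform positions (1.31, adjusted binomial p = 0.0249).

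The 310 peaks with the highest signal gave 0 gene lists past the threshold in place of 1, 9 enriched 6-mers in place of 46 and an operon-like odds ratio of 1.60 (exact p = 0.2), with fewer peaks tested. A 500 bp distance also gave 0 lists, and all annotated genes as background, which also limited the genes with a peak to protein-coding ones, gave 4 lists: ribosomal proteins, chaperones, translation factors and chemoreceptors. Protein-coding genes alone, chosen after seeing the data, gave 1 list, ribosomal proteins in place of chemoreceptors. Protein-coding transcript starts gave the same list and an operon-like odds ratio of 1.24. Enriched 6-mers numbered 14 with a 25 bp window, 150 without GC matching, 160 against flanks of the same peaks, 3 without peaks assigned to tRNA genes and 2 also without those within 100 bp of one. In the last, the odds ratio of GCTCTA on IV, V and X turned to 0.959. Without replicate 1, 28 6-mers were enriched, and 26 of them were among the 46 of the main setting. Without replicate 2, 42 were enriched, but only 20 of them were among those 46. The operon-like odds ratio was 1.39 to 1.55 with each replicate left out in turn. Of the results that passed no threshold, the odds ratio of the share in non-coding RNA exons ranged from 0.82 to 1.33 with each replicate left out and was 0.939 against uniform positions, and that of the ncRNA biotype turned to 1.08 without replicate 1 and 1.00 with nuclear peaks only. The odds ratio of GGAGCA on IV, V and X, 0.47 and past the threshold in the main setting, turned to 1.06 against flanks. Its call was also lost with the 310 highest peaks (0.407), without replicate 1 (0.587), with a 25 bp window (0.608) and without GC matching (0.706). The cause was not tested. No paired analysis was possible because the series has a single group. Read depth is unknown, so its effect on the peak lists was not assessed.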

Other observations

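The comparison of near-identical tRNA genes, that of sequence-unique tRNA genes with other genes, that of X without peaks assigned to tRNA genes and that of ncRNA summits away from tRNA genes were tests chosen only after the result was seen. Of the 88 peaks assigned to genes annotated as ncRNA, 34 had their summit within 100 bp of a tRNA gene, and 25 lay inside one. A B box was taken as GTTCGA, any 2 bases and C on either strand within 100 bp. It was present at 36.4% of the ncRNA summits (32 of 88) and at 5.46% of background summits at ncRNA genes (odds ratio 9.91, 95% interval 6.10 to 16.1). Of the 32, 29 were within 100 bp of an annotated tRNA gene, whose own B box the window can take in. The excess therefore does not show that the ncRNA genes have tRNA-like internal promoters of their own. Away from tRNA genes the B box stood at 3 of 54 ncRNA summits against 37 of 1447 background summits (odds ratio 2.56, 0.826 to 7.91), too few to decide. At snoRNA genes it was present at 17 of 63 summits and 5 of 145 background summits (odds ratio 9.61, 3.49 to 26.5), and at protein-coding genes at 3.40% and 1.48%.

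The X peaks without a transcript start within 1000 bp may be recruitment sites of the dosage compensation complex, which binds X in hermaphrodites through a motif called MEX (TCGCGCAGGGAG). An 8-base part of the motif lay within 100 bp of 11 of the 19 summits (57.9%) and of 9 of 1067 X background summits of the same kind (0.843%; odds ratio 151, 95% interval 50.5 to 450, p = 2.02e-16, Fisher's exact test). Among the 10 of these peaks with the highest signal, 7 had such a part. On autosomes it was found at 1 of 46 summits of that kind and at 40 of 4737 background summits (odds ratio 3.82, 0.73 to 20.02). Within 1000 bp of a transcript start it was present at 4.11% of X summits against 0.82% of background. Most of these 6 X summits were far from the start: -738 (nspc-17), -812 (T27A8.8), -617 (ins-39) and 596 bp (WBGene00020829). The others were at -175 (C18A11.13) and 16 bp (WBGene00023149). On autosomes the shares within 1000 bp were 2.83% and 0.867%, so part of the excess is not specific to X. The motif comparisons were not matched on GC content. Whether these peaks belong to the tagged protein or appear in any immunoprecipitation was not tested, since peak lists of other factors or of untagged animals were not used here.

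For the lead of tRNA genes, base composition argued little: against background summits matched on GC the odds ratio of tRNA genes was 24.4 (95% interval 18.1 to 32.8), compared with 40.1 before matching. Peaks were not confined to tRNA genes with an identical copy. Sequence-unique tRNA genes with a pooled region had a peak in 35 of 77 cases against 326 of 8241 other genes (odds ratio 20.3, 12.8 to 32.1). Of these 35, 15 were 1 edit from another tRNA gene and 11 were 2 to 3 edits away. Such genes may still share reads, so the comparison cannot exclude shared reads as the cause. A part played by identical copies stays open: 37.1% of the 469 nuclear genes with an identical copy had a peak against 24.5% of the 143 without, a ratio of 1.52 (p = 0.00639, Fisher's exact test). Near-identical copies stay open as well. Of 24 genes at 8 or more edits from every other tRNA gene, 1 had a peak (4.17%, Fisher's exact test, p = 0.000628 against identical copies). The share did not fall steadily with distance: 25% at 1 edit (15 of 60, exact p = 0.0852), 36.7% at 2 to 3 edits (11 of 30) and 27.6% at 4 to 7 edits (8 of 29, p = 0.329). How active the distant genes are was not measured. No biological explanation was tested, as the series has a single group.

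The excess of peaks on X lay at tRNA genes, of which 45.1% are on X. With peaks assigned to tRNA genes left out, the odds ratio of X against the autosomes was 0.987 (95% interval 0.746 to 1.30), against 2.04 (1.70 to 2.46) for all nuclear peaks. The density of tRNA genes on X need not account for all of this excess. Among tRNA genes, 38.4% of those on X and 30.7% of those on autosomes had a peak (odds ratio 1.41, Fisher's exact test, p = 0.0489).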
